A study of Arabidopsis thaliana with 208 samples.

How the data were processed

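Leaf RNA of 104 recombinant inbred lines was measured on Affymetrix tiling arrays, 1 array per line in wet soil and 1 in dry soil, 208 arrays in all. Per the labels' protocols, plants grew for 4 weeks under 12 h of light before drying began, tissue was kept in RNAlater, RNA was extracted with a column kit, and 7 ug of it was made into labelled cDNA without amplification. The blocks of the growth design were 4, of which 2 received the drying treatment by random assignment, per the series' design text. No source used here states which plants or blocks went to an array, whether plants were pooled, or when each line was harvested.

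The authors deposited 1 table with 1 value per locus and array, 25662 loci by 208 arrays, with no missing values. The deposited values were taken as log2 expression values. That scale is inferred, not stated: values run from 6.30 to 13.7, which lies inside the log2 range of a 16-bit scanner, while its natural log ends at 11.1 and its log10 at 4.82. How the authors corrected background, normalized the arrays and joined probes to a locus is not given in the sources used here. Array means lay between 7.23 and 7.29 and medians between 7.09 and 7.22, so the arrays had been brought near a common level before deposit, and no further normalization was applied. The scanner's own files were not available, so signal over background could not be assessed. The number of arrays and the spread of a gene's values among lines limit the precision.

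Locus identifiers were matched to a gene table of assembly TAIR10.1 for names and gene order alone. Of the loci, 25555 were found in it and 9485 had a symbol. All loci lay on the 5 nuclear chromosomes, and 0 belonged to a plastid or mitochondrial genome, so the planned organelle comparison between the crosses and its alternatives could not be run. The build the authors used is not stated, and no coordinates are given.

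Samples were grouped by title into KT and TK lines in wet and in dry soil. A total of 25 gene lists with 370 members were fixed before the data were examined, of which 350 were measured, 3 had a name missing from the gene table and 17 had a locus with no value. The rule for naming genes was fixed at the same time. It takes, for dry against wet soil, the 10 largest rises and the 10 largest falls with that direction in at least 75% of lines, and the 3 members of each list with the largest absolute change. It takes the 5 largest differences each way between the crosses and in the response to drying, the 10 highest correlations between soils, and the 5 largest SD ratios each way. Any gene named outside this rule was chosen after its values were seen, whether or not the sentence naming it says so.

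Dry and wet arrays were compared with limma's lmFit and eBayes, with the cross as a covariate. The crosses were compared on the mean of a line's arrays, and the response to drying was compared between crosses on the dry minus wet difference of each line, so that the line was the replicate. Differences are on the log2 scale with the model's standard error (SE). Benjamini-Hochberg adjusted p under 0.05 over all loci was the threshold, and counts at an absolute log2 change of at least 0.5 and 1 are also given. Gene lists were tested with limma's camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 25 lists. The tests of lists on the response difference were added after the data were seen.

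For differences among lines, the mean of each cross in each soil was removed. Pearson's correlation over the 104 lines between a gene's wet and dry values, called the wet-dry correlation, was tested two-sided, and equal variance in both soils was tested with the Pitman-Morgan test, both adjusted over all loci. Lists were set against 10000 random lists of the same size and matched expression. For genes with a wet-dry correlation of at least 0.5, absolute correlations of line means between pairs of genes were compared by distance in gene order with 1000 random placements of those genes. Correlations of scores across lines were tested by permutation, two-sided, and 9 such relations were adjusted together.

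Pairing by line comes from the labels, since both arrays of a pair are of the same inbred line. As a check, the correlation of the deviations of a line's wet and dry array from their group means had a median of 0.181 and ranged from -0.181 to 0.549, and it was over 0.1 in 80 of 104 lines. The unpaired fit stayed the main one for dry against wet soil, as fixed beforehand; with the line as a block it called 9060 loci.

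Alternatives fixed beforehand were median centring and quantile normalization of arrays, leaving out the 6416 loci of lowest mean, the line as a block, no covariate, the mean of the contrasts of the 2 crosses, array weights, a trended robust fit, rank tests, each cross alone, each soil alone, a random line effect (correlation 0.141), 5 principal components, Spearman's correlation, a test of absolute deviations, and other limits for the neighbour analysis. Alternatives chosen after seeing the data were other gene sets for matching arrays of a line, leaving out 2 or 20 lines that did not match themselves, leaving out line KT140, which holds the array with the lowest mean correlation with the others, and the SD of an array's values as a covariate. Each group comparison was repeated over 100 regroupings of the samples, the real one included. Soils were swapped within lines, crosses were drawn anew over lines, and for the wet-dry correlation dry arrays were re-paired with other lines.

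The tests were checked on simulated data made from the real loci. For dry against wet soil, 70% of simulated changes of 0.1 and 100% of those of 0.25 were called, with 0.035% of unchanged loci. For the crosses these shares were 58% and 96%, with 0.043%. For the response difference they were 16% and 76%, with 0.016%. A correlation of 0.3 was called in 30% of simulated genes and one of 0.5 in 94%. An SD ratio of 1.5 was called in 50% and one of 2 in 100%. Noise was drawn independently for each locus, without correlation between loci, and for the group comparisons with the same SD in both groups. The printed shares need not hold for the real arrays. Among the real regroupings, a swap of soils within lines called up to 1882 genes. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.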

Results

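Leaves of 104 recombinant inbred lines of Arabidopsis thaliana were profiled in wet and in dry soil. Such lines are near-homozygous descendants of a cross, here between the accessions Kas-1 and Tsu-1 made in both directions. Line names begin with KT (32 lines) or TK (72 lines), and the labels do not state which parent either prefix puts first. Each line had 1 array from soil held at 100% of field capacity and 1 from soil dried over about a week to 40%. Expression was read at 25662 loci of the nuclear chromosomes as log2 values, and the number of arrays limits the precision. Drying was assigned by growth block, so block and soil treatment cannot be told apart in any comparison of soils.

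The comparison of soils asks which genes a slow decline in water changed in the leaf. The transcript of RAB18 (AT5G66400), a dehydrin induced by abscisic acid (ABA), rose most, from 7.40 ± 0.38 (SD, n = 104) in wet soil to 10.92 ± 0.74 (SD, n = 104) in dry soil. That is an 11.5-fold rise, and it was seen in all but 1 of 104 lines. Transcripts of tonoplast aquaporins fell together: TIP1;1 (AT2G36830) was 3.88-fold and TIP1;2 (AT3G26520) 3.66-fold lower in dry soil (SE 0.058 and 0.071 on the log2 scale). Of 30 measured genes of photosynthesis, 27 fell and none rose, while 14 of 23 genes induced by ABA and dehydration rose.

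Among the other 9 largest rises, HIPP22 (AT1G22990), a heavy-metal-associated isoprenylated protein, rose by 2.24 (SE 0.073) and RD29B (AT5G52300), a classic desiccation-response gene, by 2.05 (SE 0.060). AT3G17520 rose in all 104 lines, by 2.00 (SE 0.084), and so did SAG29 (AT5G13170), a SWEET sugar transporter, by 1.57 (SE 0.065). The drought-induced gene DI21 (AT4G15910) rose 3.64-fold, DAA1 (AT1G64110) 3.38-fold and the annexin ANNAT1 (AT1G35720) 3.26-fold. AT3G53980 rose 3.05-fold, and HB-7 (AT2G46680), a homeodomain-leucine zipper factor induced by ABA, rose 2.87-fold. GASA1 (AT1G75750), of the gibberellin-stimulated family, had the largest fall and fell by 2.41 (SE 0.11), or 5.32-fold. The light-harvesting gene LHB1B1 (AT2G34430) fell 4.94-fold, and SEN1 (AT4G35770), a dark-inducible gene, fell in all 104 lines by 1.85 (SE 0.071). The cell wall protein PRP4 (AT4G38770) was 3.20-fold lower in dry soil, the aquaporin TIP2;1 (AT3G16240) 3.12-fold, and the beta-galactosidase BGAL1 (AT3G13750) 3.08-fold. The germin-like GER1 (AT1G72610) was 2.88-fold and AT2G10940 was 2.86-fold lower. Each of these falls was seen in at least 97 of 104 lines. AT3G17520, DI21 and DAA1 averaged 6.89, 6.98 and 6.89 in wet soil, below the median of all values (7.15). Without a measure of background, the printed change of a gene at such low values, in this list or a later one, does not give the size of the change in transcript.

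**Figure D1:**
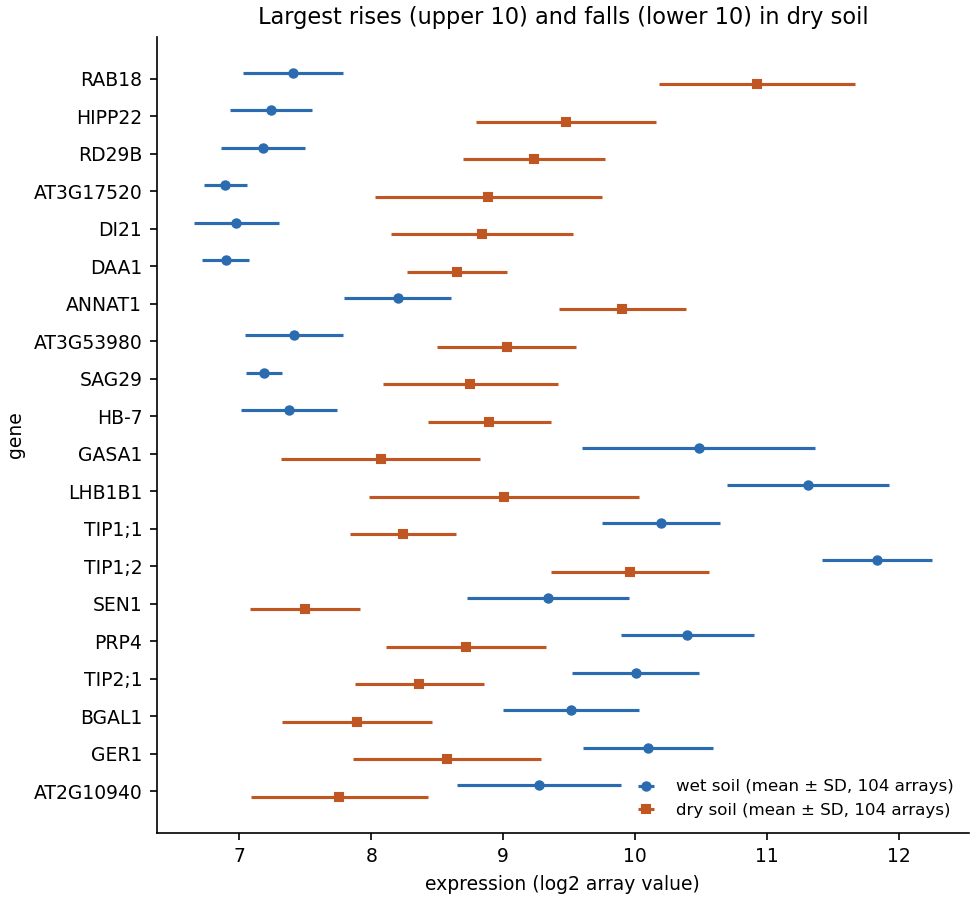
Expression (log2 array value) of the genes with the 10 largest rises and the 10 largest falls; points are means over 104 arrays per soil and bars are the SD. RAB18 moved from 7.40 to 10.92, and GASA1 from 10.48 to 8.07.

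Genes of the ABA response moved in both directions. In the list of ABA and dehydration-induced genes, 14 of 23 rose, 3 fell and 6 did not pass (18 passed when adjusted over the list alone), and camera placed the list above other genes (adjusted p = 1.27e-17). RD29B, RAB18 and DI21 led it. ERD1 (-0.35), COR47 (-0.16) and ERD10 (-0.16), chosen after their values were seen, fell. Of 9 clade A PP2C phosphatases, which hold ABA signalling in check, 8 rose and none fell (8 adjusted over the list alone; adjusted p = 1.10e-13). HAI2 rose in all but 3 of 104 lines, PP2CA rose by 0.98 (SE 0.050) and HAI1 by 0.65 (SE 0.048). Of 17 ABA receptors, SnRK2 kinases and ABF factors, 8 rose and 5 fell (13 adjusted over the list alone; adjusted p = 0.120). The receptor gene PYL8 fell by 0.52 (SE 0.037), while the factors ABF2 and ABF4 rose by 0.43 (SE 0.030) and 0.33 (SE 0.034). Among 11 genes of ABA synthesis and breakdown 3 rose and 2 fell (6 adjusted over the list alone; adjusted p = 0.212). BGLU18, which releases ABA from its glucose ester, rose by 1.23 (SE 0.11), and the ABA hydroxylases CYP707A1 and CYP707A3 rose by 0.64 (SE 0.037) and 0.51 (SE 0.056).

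Genes of compatible solutes and other stress responses also moved. In proline and raffinose metabolism 6 of 13 genes rose and 5 fell (11 adjusted over the list alone; adjusted p = 0.0545). P5CS1, the rate-limiting enzyme of proline synthesis, rose by 1.42 (SE 0.077) and the galactinol synthase GOLS2 by 1.11 (SE 0.064), while DIN10 fell by 1.15 (SE 0.064). Of 8 DREB and CBF factors 5 rose and none fell (5 adjusted over the list alone; adjusted p = 0.000150, and adjusted p = 0.0558 with an estimated correlation). ZAT10 rose by 0.83 (SE 0.072), DREB2A by 0.72 (SE 0.058) and ZAT12 by 0.61 (SE 0.061). Of 10 heat shock genes 6 rose and none fell (6 adjusted over the list alone; adjusted p = 0.00460, and adjusted p = 0.143 with an estimated correlation). HSP70 (AT3G12580) rose by 1.13 (SE 0.071), HSP90.1 by 0.39 (SE 0.067) and HSFA2 by 0.30 (SE 0.047). Antioxidant enzymes split evenly, with 4 of 10 up and 4 down (8 adjusted over the list alone; adjusted p = 0.814). The catalase genes moved apart, CAT3 by 0.33 (SE 0.053) and CAT2 by -0.31 (SE 0.067), and the superoxide dismutase gene FSD1 fell by 0.29 (SE 0.039). In the wax and cuticle list 5 of 15 rose and 4 fell (9 adjusted over the list alone; adjusted p = 0.806), with CUT1 at -0.31 (SE 0.047), CER1 at 0.25 (SE 0.051) and LTPG1 at -0.21 (SE 0.042).

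Genes of photosynthesis, water transport and wall loosening fell. At the preset correlation the photosynthesis list had the smallest camera p of the 25 lists (adjusted p = 4.88e-31). Of its 30 genes 27 fell, and 28 passed when adjusted over the list alone. With an estimated correlation its camera adjusted p was 0.0173, and aquaporins had the smallest (5.31e-07). PSAK fell by 1.02 (SE 0.085), LHCB6 by 0.94 (SE 0.085) and PRK, the phosphoribulokinase of the Calvin cycle, by 0.92 (SE 0.062). Of 17 aquaporins 15 fell and 2 rose (17 adjusted over the list alone; adjusted p = 1.19e-29). PIP2;5 rose by 0.57 (SE 0.042) and PIP1;4 by 0.13 (SE 0.034), both chosen after their values were seen, while PIP2;1 fell in 104 of 104 lines. Of 20 expansins and xyloglucan hydrolases 12 fell and 3 rose (15 adjusted over the list alone; adjusted p = 3.20e-07). XTH24 fell by 1.45 (SE 0.093) and XTH6 by 0.98 (SE 0.037), and TCH4, a touch-induced member, rose by 1.07 (SE 0.079). In DNA replication and cell division 6 of 13 fell and 1 rose (9 adjusted over the list alone; adjusted p = 0.0248, and adjusted p = 0.222 with an estimated correlation). The changes were small, with MCM7 at -0.13 (SE 0.017), MCM3 at -0.11 (SE 0.020) and PCNA1 at -0.10 (SE 0.020).

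Metabolic and defence lists were mixed. Of 25 glucosinolate genes 17 fell and 1 rose (18 adjusted over the list alone; adjusted p = 0.000365, and adjusted p = 0.179 with an estimated correlation). The exception was ESP (AT1G54040), the epithiospecifier protein, which rose by 0.71 (SE 0.069), while the myrosinase TGG2 fell by 0.56 (SE 0.13) and MAM3 by 0.52 (SE 0.065). In starch and sugar 4 of 12 rose and 6 fell (10 adjusted over the list alone; adjusted p = 0.521). The beta-amylase BAM3 fell by 0.97 (SE 0.055), and APL3, a starch synthesis subunit, and the glucose-phosphate translocator GPT2 rose by 0.75 (SE 0.037) and 0.74 (SE 0.057). In the senescence list 3 of 13 rose and 5 fell (9 adjusted over the list alone; adjusted p = 0.0309, and adjusted p = 0.179 with an estimated correlation). SAG29 rose, SEN1 fell, and ASN1, an asparagine synthetase, fell 2.38-fold. Of 21 salicylic acid and defence genes 5 rose and 7 fell (13 adjusted over the list alone; adjusted p = 0.343), with ACD6 at -1.12 (SE 0.090), WRKY40 at 0.62 (SE 0.079) and WRKY18 at 0.43 (SE 0.075). Of 16 jasmonate genes 7 rose and 5 fell (12 adjusted over the list alone; adjusted p = 0.449), with LOX2 at -1.20 (SE 0.090), JAZ1 at 0.61 (SE 0.076) and JAZ9 at -0.55 (SE 0.067). Flavonoid genes moved little (3 of 14 rose and 1 fell, 4 adjusted over the list alone; adjusted p = 0.290), with PAL1 at -0.34 (SE 0.029), F3H at 0.31 (SE 0.043) and PAP1 at 0.24 (SE 0.031).

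Marker and reference lists were read as checks on tissue and scaling. In the circadian clock list 3 of 15 rose and 2 fell (6 adjusted over the list alone; adjusted p = 0.701), with CCA1 at 0.22 (SE 0.067), RVE8 at 0.22 (SE 0.046) and GRP7 at 0.24 (SE 0.10), whose call ended with median centring and without line KT140. Flowering regulators (1 of 9 up, 1 down, 3 adjusted over the list alone; adjusted p = 0.896) included FD at -0.07 (SE 0.029), which passed but did not without line KT140 or in either cross alone, and SVP at -0.06 (SE 0.025) and the floral repressor FLC at 0.12 (SE 0.054), which did not. With the line as a block FLC and SVP passed (adjusted p = 0.000194 and 0.0452). The median of the root markers was -0.00149, and the camera direction was up (1 of 9 up, 1 down, 2 adjusted over the list alone; adjusted p = 0.896). COBL9 stood at 0.11 (SE 0.020) and SHR at -0.07 (SE 0.017). Floral and meristem markers had 2 of 8 up (1 adjusted over the list alone; adjusted p = 0.652), with PI at 0.08 (SE 0.021). Guard cell markers had 3 of 7 down (3 adjusted over the list alone; adjusted p = 0.262), led by the potassium channel KAT1 at -0.13 (SE 0.018). Among 5 reference genes 3 fell (4 adjusted over the list alone; adjusted p = 0.000910, and adjusted p = 0.0501 with an estimated correlation). ACT2 fell by 0.59 (SE 0.039), ACT8 by 0.50 (SE 0.040) and YLS8 by 0.21 (SE 0.040), and these kept their sign under median centring and quantile normalization.

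**Figure D2:**
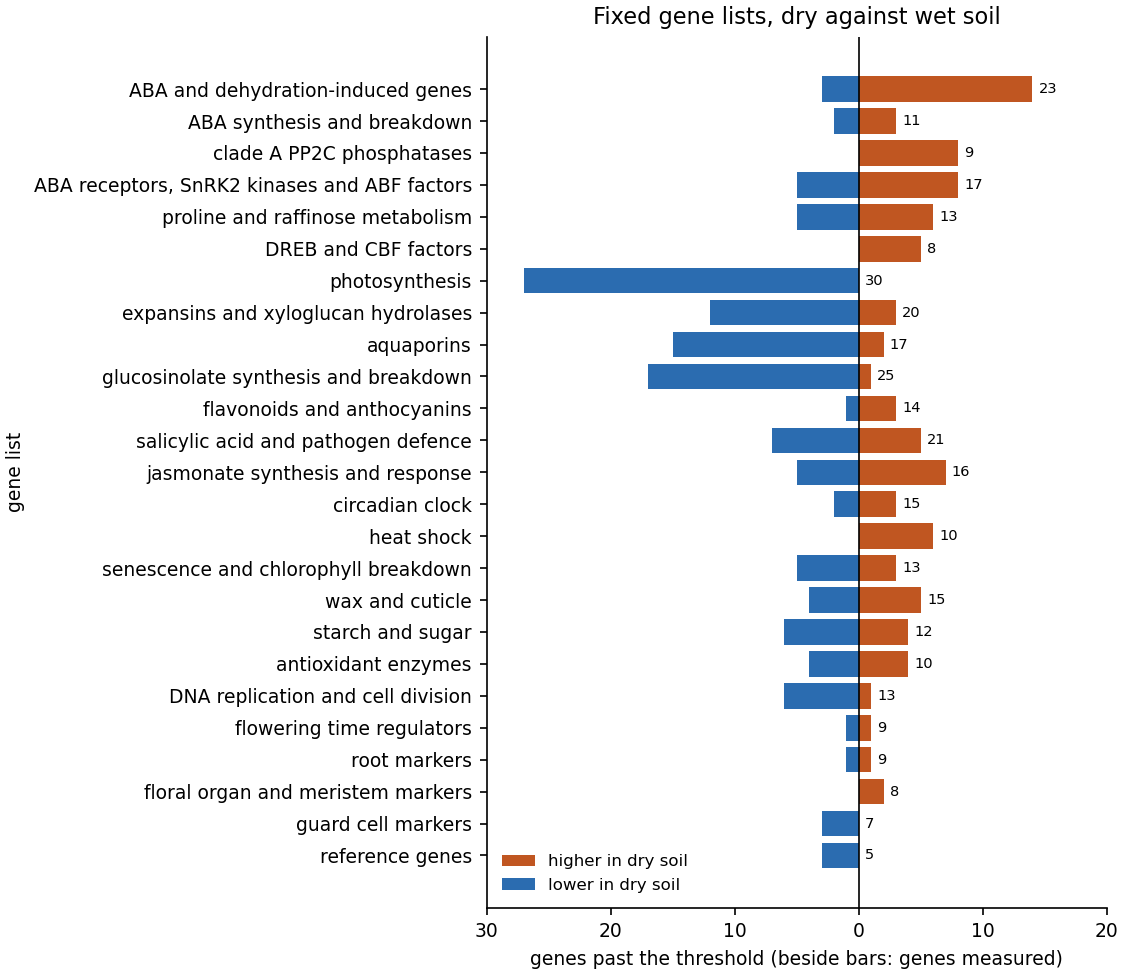
Genes of each fixed list that were higher (right) or lower (left) in dry than in wet soil at adjusted p under 0.05, with the number measured beside the bars. Photosynthesis (27 of 30), aquaporins (15 of 17) and glucosinolate genes (17 of 25) lie mostly on the lower side.

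Over all loci, limma called 8426 genes, 4216 higher and 4210 lower in dry soil, with n = 104 arrays per soil. Most changes were small, since 450 genes changed by at least 0.5 and 74 by at least 1 on the log2 scale. Camera called 11 of 25 lists, of which 5 held with an estimated correlation (ABA and dehydration, PP2C, photosynthesis, expansins and xyloglucan hydrolases, and aquaporins). Arrays of dry soil had a lower SD (0.463 against 0.473, permutation test p = 0.00382) and a lower mean (7.257 against 7.260, p = 0.0012) than those of wet soil. In the KT lines alone, which are fewer, 3443 genes were called, and CCA1, RVE8, TGG2, YLS8, CAT2 and FSD1 were among the genes that did not pass there.

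The KT and TK lines came from reciprocal crosses, and their comparison asks whether the direction of the cross marks a difference in nuclear expression. TK lines had higher transcripts of glucosinolate synthesis. Runs of TK lines with neighbouring names, set against all other lines, also differed in this list (smallest camera p 1.12e-11, against 6.32e-17 for the crosses). Those other lines include every KT line, so the runs do not tell name order and cross apart. BCAT4 (AT3G19710), which starts methionine chain elongation, was at 7.61 ± 0.34 (SD, n = 32) in KT and 8.08 ± 0.45 (SD, n = 72) in TK lines, and CYP79F1 (AT1G16410), the aldoxime-forming enzyme, was higher by 0.40 (SE 0.078). Of 25 glucosinolate genes 8 were higher in TK and none lower (13 adjusted over the list alone; adjusted p = 1.58e-15, and adjusted p = 0.00441 with an estimated correlation). All differences were modest, the largest being 1.42-fold.

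BGLU18 (AT1G52400) was higher in TK by 0.50 (SE 0.13), TCTP (AT3G16640) by 0.41 (SE 0.088) and the jasmonate-responsive JR1 (AT3G16470) by 0.41 (SE 0.11). Higher in KT were AT1G15010 (-0.33, SE 0.087), AT5G16030 (-0.25, SE 0.068), AT4G36500 (-0.23, SE 0.060), the shade-response factor HB-2 (AT4G16780; -0.23, SE 0.055) and the inositol oxygenase MIOX2 (AT2G19800; -0.20, SE 0.054). Among the other list members that passed, chosen after their values were seen, were MYB28, the regulator of aliphatic glucosinolate synthesis, by 0.21 (SE 0.041), MAM3 by 0.34 (SE 0.075), CYP83A1 by 0.32 (SE 0.064) and SOT18 by 0.22 (SE 0.040). The sucrose exporters SWEET11 and SWEET12 were higher by 0.21 (SE 0.059) and 0.28 (SE 0.062), and the starch and sugar list was called (2 of 12 higher in TK, 5 adjusted over the list alone; adjusted p = 2.57e-06, and adjusted p = 0.0124 with an estimated correlation). Reference genes were called as well (2 of 5, 3 adjusted over the list alone; adjusted p = 3.14e-05, and adjusted p = 0.0214 with an estimated correlation), with ACT2 higher by 0.21 (SE 0.050) and UBQ10 by 0.20 (SE 0.050).

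Another 7 lists, all higher in TK, were called at the preset correlation and not with an estimated one. Of these, fry also called ABA and dehydration-induced genes, PP2C phosphatases, ABA receptors with their kinases and factors, and wax and cuticle (adjusted p = 0.0416 for each). They were ABA and dehydration-induced genes (adjusted p = 2.57e-06, and adjusted p = 0.124 with an estimated correlation), wax and cuticle (0.000121 and adjusted p = 0.124 with an estimated correlation), clade A PP2C phosphatases (0.000324 and adjusted p = 0.124 with an estimated correlation), and ABA receptors, SnRK2 kinases and ABF factors (0.0218 and adjusted p = 0.0866 with an estimated correlation). The others were aquaporins (0.0240 and adjusted p = 0.426 with an estimated correlation), the circadian clock (0.0240 and adjusted p = 0.162 with an estimated correlation) and antioxidant enzymes (0.0454 and adjusted p = 0.212 with an estimated correlation). In these 7 lists, RD22 (0.34, SE 0.082) and CUT1 (0.30, SE 0.058) were the members that passed over all loci.

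Over all loci limma called 468 genes between the crosses, 274 of them higher in TK (58.5%) and the others lower. The split moved with scaling: 345 genes with 75.7% higher after median centring, 336 with 72.3% after quantile normalization, and 342 with 78.9% without the loci of lowest mean. With the SD of the array as a covariate, chosen after the data were seen, it turned to 577 genes with 48% higher in TK. Wet arrays alone ended the calls of BGLU18, TCTP, JR1, AT1G15010, AT5G16030, AT4G36500 and HB-2, and dry arrays alone those of BGLU18, BCAT4, JR1, CYP79F1, AT5G16030, AT4G36500, HB-2 and MIOX2. The rank-sum test called 243, and wet or dry arrays alone gave 92 and 148. Array values spread slightly less in KT (SD 0.460, n = 32) than in TK lines (0.472, n = 72; permutation test p = 0.0845), array means were 7.260 in KT and 7.257 in TK (p = 0.0357), and the difference between crosses rose with expression level (r = 0.376 across genes, which are not independent replicates; 0.175 after quantile normalization and 0.107 with the SD of the array as a covariate).

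The response to drying differed between the crosses at 9 genes, 2 of them in the fixed list of salicylic acid and pathogen defence. BGL2 (AT3G57260), the beta-glucanase PR2, changed by 0.61 ± 0.92 (SD, n = 32) in KT and by -0.16 ± 0.54 (SD, n = 72) in TK lines. PR5 (AT1G75040), a thaumatin-like protein, changed by 0.27 ± 0.75 (SD, n = 32) and -0.38 ± 0.53 (SD, n = 72). PR5 was lower in dry soil in 57 of 72 TK lines and in 11 of 32 KT lines. The difference in response was -0.78 (SE 0.14; adjusted p = 0.00305) for BGL2 and -0.65 (SE 0.13; adjusted p = 0.00714) for PR5. The fit assumes the same spread in both crosses, but the SD of both genes was larger in KT, the smaller group. Their SE and adjusted p may therefore be too small. Line KT140 had the largest change of both, 3.34 for BGL2 and 2.32 for PR5, and its wet array had the lowest mean correlation with the other arrays (0.676). Without this line, a setting chosen after the data were seen, BGL2 changed by 0.52 ± 0.79 (SD, n = 31) in KT lines, BGL2 and PR5 still passed (adjusted p = 0.0101 and 0.0236), and AT3G50650 and CRT3 did not (adjusted p = 0.0822 for each).

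The aspartyl protease gene AT5G10760 (-0.49, SE 0.091), the calreticulin CRT3 (AT1G08450; -0.42, SE 0.092) and RING1 (AT5G10380; -0.33, SE 0.065), a ring-finger ubiquitin ligase, also responded lower in TK lines. So did AT4G36052 (-0.24, SE 0.051) and BGLU33 (AT2G32860; -0.18, SE 0.039), which lie outside the naming rule and were chosen after their values were seen. The response was higher in TK for KCS19 (AT5G04530), of the fatty acid elongase family (0.27, SE 0.046), which rose by 0.31 in TK and by 0.04 in KT lines, and for AT3G50650 (0.16, SE 0.034). In the list of salicylic acid and pathogen defence 2 of 21 genes passed, both lower in TK (6 adjusted over the list alone; adjusted p = 5.62e-05, and adjusted p = 0.164 with an estimated correlation). The receptors, SnRK2 kinases and ABF factors of ABA signalling responded higher in TK as a list (adjusted p = 0.00297, and adjusted p = 0.0205 with an estimated correlation), with 0 of 17 members passing alone and 2 adjusted over the list alone. Called only at the preset correlation were glucosinolate genes, lower in TK (adjusted p = 4.50e-06, and adjusted p = 0.184 with an estimated correlation), jasmonate genes (0.00253, and adjusted p = 0.498 with an estimated correlation) and photosynthesis (0.00297, and adjusted p = 0.806 with an estimated correlation). Also called only at the preset correlation was the circadian clock, which responded higher in TK (0.0355, and adjusted p = 0.428 with an estimated correlation). So were aquaporins, lower in TK (0.0418, and adjusted p = 0.778 with an estimated correlation). At an unadjusted p under 0.05, 1990 loci differed in response. The interaction term without pairing by line called 2 genes and the rank-sum test called 1.

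**Figure D3:**
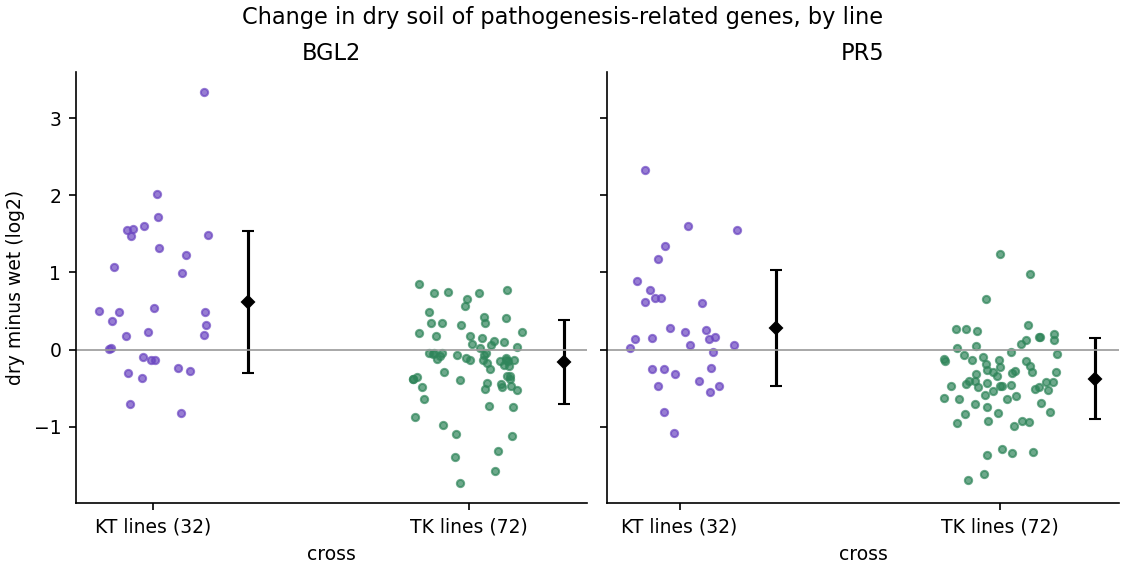
Dry minus wet expression (log2) of BGL2 and PR5 in each of 32 KT and 72 TK lines; diamonds and bars are the mean and SD. The mean for BGL2 is 0.61 in KT and -0.16 in TK lines, with overlap between the crosses.

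The design also asks which differences among lines hold in both soils. UBQ11 (AT4G05050), a polyubiquitin gene, kept its array value in each line most closely, with a wet-dry correlation of 0.927 over 104 lines. Its lines fell at 2 levels, 59 low and 45 high, 1.64 apart on the log2 scale, and all but 2 of 104 lines lay on the same side in both soils. This split was chosen after the values were seen. Sequence differences between the parents at the array's probes were not assessed. For this gene and those below, low and high array values therefore need not be low and high transcript levels. Within the low and the high lines the correlation was 0.419 and 0.544. The immune receptor gene SNC1 (AT4G16890) had a wet-dry correlation of 0.892, with 40 low and 64 high lines, 1.49 apart.

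A neighbouring pair of immune receptor genes, DAR4 (AT5G17890) and CSA1 (AT5G17880), followed at 0.880 and 0.866, and each had 60 low and 44 high lines. The other 6 of the 10 highest had locus names alone: AT1G23960 (0.920), AT2G11240 (0.917), AT2G05915 (0.898), AT3G57470 (0.863), AT3G18535 (0.861) and AT2G13665 (0.858). In each of these 10 genes at least 92 of 104 lines lay on the same side in both soils. Of the 25 lists, the circadian clock alone had a median wet-dry correlation beyond matched random lists after adjustment (0.533 against 0.200). Its adjusted p against those lists was 0.0025, the smallest that the draws allow. Random lists were not matched on correlation between members. Clock genes varied together over lines, so this p may be too small. LHY (0.753), GI (0.686), FKF1 (0.671), GRP7 (0.631) and CCA1 (0.618) were among the 14 of 15 clock genes that passed (14 adjusted over the list alone), and ZTL (0.155) was the exception. After removal of 5 principal components the median of the clock genes was 0.279, with LHY at 0.403, GI at 0.340 and CCA1 at 0.163. In wet soil CCA1 and LHY, the morning genes, correlated at 0.905 over lines, and CCA1 went against the evening genes GI (-0.602) and TOC1 (-0.506). The first component of the clock genes correlated between the soils over lines (Pearson's r = 0.725, Spearman's rho = 0.724, permutation p = 1e-05 for each, the smallest they can give; adjusted p = 1.8e-05 over 9 relations). Without the 2 lines farthest from the median, r was 0.726.

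**Figure D4:**
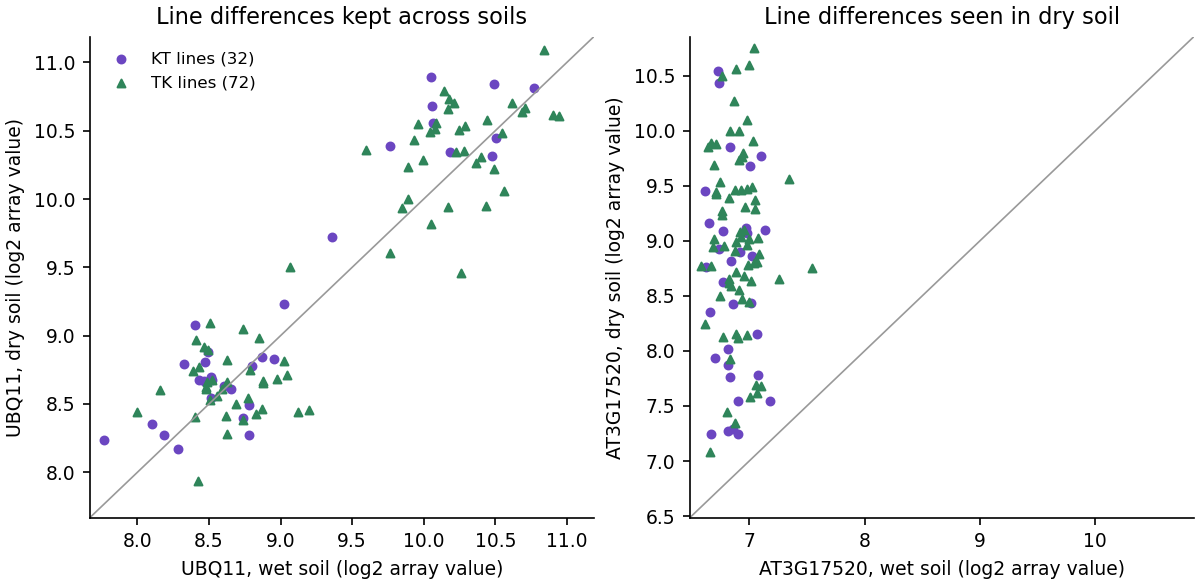
Each point is a line, 32 KT and 72 TK, with its log2 array value in wet soil on the x axis and in dry soil on the y axis; the grey line marks equal values. UBQ11 keeps 2 levels in both soils (wet-dry correlation 0.927), while AT3G17520 values spread more among lines in dry soil (SD 0.16 in wet and 0.84 in dry soil).

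Clock genes also resembled those of lines with neighbouring names. The median correlation of the 15 clock genes between a line's wet array and its own dry array was 0.533, and with the dry array of the line 1 place later in name order it was 0.277. It was 0.163 at 2 places, 0.214 at 3 and -0.043 at 5 places. For LHY the values at 1, 2 and 3 places were 0.517, 0.303 and 0.173. The median over all genes was 0.138 for a line's own arrays and 0.0286 at 1 place. This comparison was chosen after the data were seen. At 1 place later 19 genes passed over all loci, against 6108 for a line's own arrays.

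**Figure D5:**
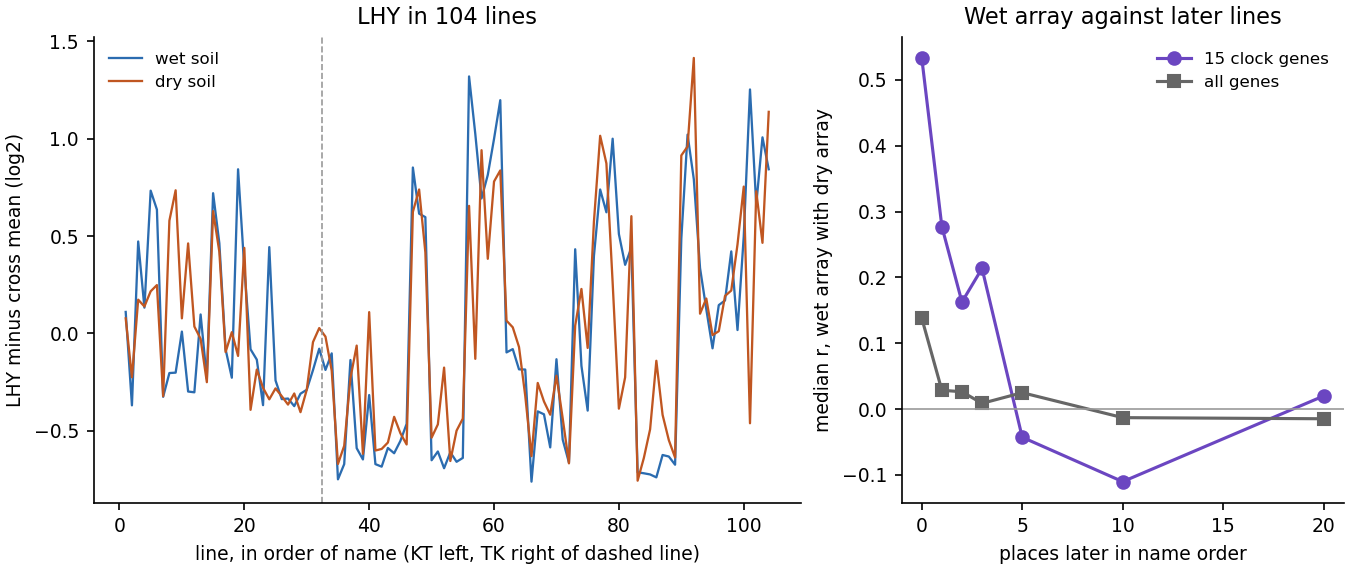
Left, LHY expression (log2, mean of the cross removed) in wet and dry soil for 104 lines in order of name; right, median wet-dry correlation of 15 clock genes and of all genes when the dry array is taken from a line later in that order. The clock median is 0.533 for the same line and 0.277 at 1 place later.

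Over all loci 6108 genes had a wet-dry correlation past the threshold, 6100 of them positive; 451 reached 0.5 and 19 reached 0.8. The called genes fell to 732 after removal of 5 principal components and to 2338 with the SD of the array as a covariate. The array SD of a line correlated between its wet and dry arrays (Pearson's r = 0.484, permutation adjusted p = 1.8e-05). It also followed the first component of the arrays (r = 0.913 in wet and -0.929 in dry soil, the sign being arbitrary). Part of the 6108 may thus reflect a spread shared by a line's arrays, which was not separated from differences at single genes. Over the 500 most variable genes, 47 of 104 wet arrays correlated best with the dry array of their own line; gene sets chosen after seeing this gave 76, 96 and 97, and all but 3 once 5 principal components had been removed.

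Array values varied more among lines in dry than in wet soil at 832 genes and less at 480. The late-embryogenesis gene AT3G17520 had an SD among lines of 0.16 in wet and 0.84 in dry soil, a ratio of 5.13. AT2G42560 (ratio 5.10), SAG29 (4.74), PIL2 (AT3G62090; 3.17), a phytochrome-interacting factor-like gene, and AT3G28270 (3.05) also varied more in dry soil. Variation was larger in wet soil for PPT2 (AT3G01550; ratio 0.380), a phosphoenolpyruvate translocator, the receptor kinase IOS1 (AT1G51800; 0.384), the arginase ARGAH2 (AT4G08870; 0.437), AT4G32460 (0.440) and the beta-glucanase BG3 (AT3G57240; 0.451). AT3G17520 averaged 6.89 in wet soil and PPT2 6.99 in dry soil, below the median of all values (7.15). Without a measure of background, a ratio against an SD at such low values does not give the size of a change in line variance.

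There were 4 lists that stood apart from matched random lists in this ratio. Photosynthesis genes varied more in dry soil (10 of 30 called larger in dry, none larger in wet, 17 adjusted over the list alone; adjusted p = 0.000833), as did heat shock genes (5 of 10, 5 adjusted over the list alone; adjusted p = 0.000833). HSFA2 had a ratio of 2.07 and RCA, rubisco activase, of 1.55. In the list of ABA receptors, SnRK2 kinases and ABF factors 5 of 17 varied more in dry soil (7 adjusted over the list alone; adjusted p = 0.0106), with an SD of 0.15 in wet and 0.32 in dry soil for ABF4 and a ratio of 1.83 for ABF2. Glucosinolate genes varied more in wet soil (8 of 25 larger in wet, none larger in dry, 14 adjusted over the list alone; adjusted p = 0.000833), with an SD of 0.31 in wet and 0.16 in dry soil for FMO GS-OX1 and a ratio of 0.611 for TGG2. The members given here were chosen after their values were seen. FMO GS-OX1 averaged 7.03 in KT and 7.07 in TK lines in dry soil, below the median of all values (7.15). Its SDs therefore do not give the size of a change in line variance. Random lists were matched on mean expression over both soils, not on the change between them. They were not matched on correlation between members either, so p may be too small for lists whose genes vary together. Over all loci the Pitman-Morgan test called 1312 genes, and 739 after removal of 5 principal components.

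Array values of genes close together on a chromosome varied together over lines. Among the 451 genes with a wet-dry correlation of at least 0.5, 30 pairs of next loci had a median absolute correlation of 0.776 ± 0.268 (SD over pairs), against 0.232 in random placements (permutation p = 0.001, the smallest they can give). The median was 0.397 over 84 pairs 2 to 10 loci apart and 0.295 over 2997 pairs between 100 and 500 loci apart. It was 0.225 for pairs on different chromosomes. With the lower limit of 0.3 the median of next loci was 0.353, against 0.288 for pairs on different chromosomes. Random placements were made at the limit of 0.5 alone.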

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

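The tests without line KT140, of place in name order, of the spread of array values, of gene lists on the response and of regroupings of the lines were chosen after the results were seen. The test on medians was chosen before its result was seen.

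These 9 genes are given because the test of the difference itself, TK minus KT lines in the dry minus wet change, passed the threshold (n = 32 and 72 lines). It was 0.27 for KCS19 and 0.16 for AT3G50650. It was -0.78 for BGL2, -0.65 for PR5 and -0.49 for AT5G10760. It was -0.42 for CRT3, -0.33 for RING1, -0.24 for AT4G36052 and -0.18 for BGLU33. Of 100 regroupings of the lines, the real one included, 1 gave 9 genes or more, and the highest of the others gave 1, so chance assignment of lines to crosses can be excluded. For the 7 lists called on the same difference, 5 of 100 regroupings gave as many and the highest other gave 9. Chance therefore cannot be excluded for the number of lists. List by list, a camera p as small came up in 10 to 39 of 100 for photosynthesis, aquaporins, jasmonate genes and the clock. It came up in 1 to 3 for ABA receptors, kinases and factors, the defence list and glucosinolate genes.

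The mean change of BGL2 and of PR5 with drying was positive in KT and negative in TK lines. Of the 21 members of the defence list these 2 passed the test of the difference over all loci and 6 did over the list alone. As a list its response was lower in TK by camera (adjusted p = 5.62e-05, and adjusted p = 0.164 with an estimated correlation) and by fry (adjusted p = 0.0459). A few lines with extreme changes are not the whole cause for BGL2, since the difference of medians was -0.556, against -0.78 for the means and -0.69 for the means without line KT140, whose wet array was least like the others, although the rank-sum test did not pass for BGL2 (adjusted p = 0.157). Without that line 7 of the 9 genes kept their call, and AT3G50650 and CRT3 did not (adjusted p = 0.0822 for each). A difference in the spread of array values is not the whole cause either, since all 9 genes kept their call with the SD difference as a covariate. The place of lines in name order stays open. There were 21 runs of 32 neighbouring lines that hold no KT line. Their highest count of genes with a different response was 14, and 1 run had at least 9. Each run was set against all other lines, every KT line included, and the runs overlap. The counts may thus hold part of the cross difference, and they do not tell name order and cross apart. Runs that mixed the crosses gave 0 to 69 genes, against 9 for the crosses themselves. The run with 69 held 18 KT lines. The direction of the cross, including the cytoplasm, was not tested apart from name order, and no organelle locus was measured.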

How the results depend on the processing

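The alternatives without 1 line (KT140), 2 or 20 lines, with the SD of an array's values as a covariate and with the most repeatable genes for matching arrays, the neighbour analysis after removal of 5 components and all list tests on the response were chosen after the data were seen.

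For dry against wet soil the count of genes lay between 7683 and 9432 under every alternative run but one: the KT lines alone gave 3443, with fewer samples. Of the values of named genes under alternatives, 1263 kept direction and side of the threshold, 13 came to pass it and 25 no longer did. Pairing by line as a block gave 9060 genes and changed the calls of FLC and SVP and no other call of a named gene or list. Of 25 lists, 5 were called with an estimated correlation and 18 by fry. Lists that turned direction stayed above the threshold throughout: antioxidant enzymes with quantile normalization (adjusted p = 0.855) and the SD covariate (0.767; range 0.340 to 0.904), floral markers without the genes of lowest mean (0.860; range 0.0898 to 0.860), and with the SD covariate wax and cuticle (0.999; range 0.450 to 0.999) and root markers (0.811; range 0.727 to 0.963). The cause was not tested.

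Between the crosses, counts lay between 329 (without line KT140) and 577, except for wet arrays alone (92), dry arrays alone (148), each with fewer arrays per line, and the rank-sum test (243). Named genes kept direction and call in 91 values and lost the call in 19. With an estimated correlation 3 lists were called. Direction turned for flavonoids with fry (0.936; range 0.671 to 0.936), and with the SD covariate for photosynthesis (0.00449, past the threshold and lower in TK; range 0.00449 to 0.936), flowering regulators (0.810; range 0.623 to 0.989) and root markers (0.938; range 0.210 to 0.938). The cause was not tested.

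For the response, counts lay between 7 and 11, but were 2 with no replicate block and 1 with the Wilcoxon rank-sum test. Named genes kept the call in 58 values and lost it in 23. Of the lists, 1 was called with an estimated correlation (camera) and 2 by fry. DNA replication turned direction with fry (0.924) and without line KT140 (0.922; range 0.863 to 0.994). The cause was not tested.

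For wet-dry correlations, counts past the threshold lay between 5177 and 7696, but were 732 without 5 components, 2338 with the SD covariate, 1027 in KT lines and 3668 in TK lines. Genes at 0.5 or more were 1.76% of all loci, and 0.46% without 5 components, 0.795% with the SD covariate, 5.27% in KT lines and 4.95% without 20 lines unmatched over 200 genes; the other settings gave 1.54% to 1.93%. Draws of 32 TK lines gave a median of 1101 such genes (547 to 1795), against 1353 in the KT lines, so the fewer lines can give the KT count. The 20 lines were chosen because their wet and dry arrays did not match each other, so leaving them out can itself raise the correlations. That setting also gave the 7696 called genes. The cause of the other shifts was not tested. The 10 named genes kept their call in 90 values. Wet arrays matched their own line in 45.2% of lines (40.4% to 51% over the planned sets), in 73.1%, 93.3% and 92.3% with the 200, 50 and 30 most repeatable genes, and in 97.1% with 50 and 97.1% with 100 such genes without 5 components.

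For variance among lines, counts lay between 1109 and 1442, but were 739 without 5 components (452 larger in dry, 287 in wet) and 560 with absolute deviations (363 and 197). The 10 named ratios kept their call in 60 values. Neighbouring genes correlated at 0.353 with the limit of 0.3 (0.288 for pairs on different chromosomes), and genes 11 to 100 loci apart at 0.657 without 5 components. The cause was not tested. Organelle and nuclear-only settings were not run, as 0 organelle loci were present, nor was the one on shared descriptions, as no descriptions were available. Signal over background could not be assessed.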

Other observations

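The tests of tissue order, processing order, place in name order, spread of array values and regroupings were chosen after the results were seen. The test on shared alleles was chosen before its result was seen.

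Clock genes were alike in lines with neighbouring names. The median next-line correlation of the 15 clock genes, both directions averaged, was 0.264, against a highest of 0.164 in 2000 shuffled orders. Tissue taken in name order over hours of the day may give this, but cannot be told apart from other orderings: CCA1 correlated with GI of the next line at -0.15, on the limit set for it, and harvest times are not given. Processing of arrays in name order is a candidate explanation too, since 13 of the 24 other lists had next-line medians with an adjusted p under 0.05 in shuffled orders, although smaller ones, and 2 of these, wax and cuticle (0.153) and ABA receptors, kinases and factors (0.0938), lay above their highest shuffled order. Alleles shared by lines with neighbouring names cannot be told apart either. The test took 118 genes with a wet-dry correlation of at least 0.5 after removal of 5 components. They were assumed to mark alleles, since no genotypes were used. Their median was 0.041, above shuffled orders (permutation p = 0.0025). It was under the limit of 0.05 set beforehand by less than the SD of shuffled medians, 0.0172.

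The KT and TK lines differed at 468 genes, and 1 of 100 regroupings of lines gave as many, with 3 the highest other, so chance assignment of lines can be excluded. For their 10 called lists 7 of 100 gave as many, with 12 the highest other, so chance cannot be excluded for that number. Taken by itself, the glucosinolate list had as small a camera p in 1 of 100, as did starch and sugar and the reference genes. Among the other called lists it was 3 of 100 for ABA receptors, kinases and factors. It was 5 for wax and cuticle and 7 to 21 for the rest, so chance cannot be excluded for those. For glucosinolate genes, runs of lines with no KT line reached 1.12e-11. Those runs were set against groups that hold every KT line. They do not tell name order and cross apart, so name order stays open for this list too. In runs that mixed the crosses its camera p lay between 2.03e-17 and 0.964, against 6.32e-17 for the crosses. The smallest came from a run with 26 KT lines. Regroupings ignore name order. Of 21 runs of 32 neighbouring lines with no KT line, 7 gave at least 468 genes and the highest gave 2410. These runs overlap, so the 7 are not separate cases, and their counts may hold part of the cross difference. A count above that of the crosses points to a structure of the samples along name order. Such a structure may account for the 468 genes, but name order and cross were not separated. A difference in the spread of array values is not the whole cause, since 316 of the called genes kept their call with the SD covariate. The direction of the cross stays open and was not tested apart from name order.

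For dry against wet soil, 1 of 100 regroupings that swapped soils within lines gave 8426 genes or more, and the highest other gave 1882. Chance labelling of the 2 arrays of a line can thus be excluded for the count of genes. Swaps within lines cannot exclude a difference between growth blocks, since drying was assigned by block. For the number of lists, 11, it was 1 of 100, but the highest other gave 10. That number lies beyond the regroupings only narrowly, so chance is not firmly excluded for it. List by list chance cannot be excluded for 4 of the 11. A camera p as small came up in 11 of 100 regroupings for glucosinolate genes, 12 for DNA replication, 7 for senescence and 6 for heat shock. For the 6108 wet-dry correlations it was 1 of 100 re-pairings (highest other 2), and for the 1312 variance differences 1 of 100 (highest other 25). A second set of random draws, not kept, put the share for the lists of the crosses under the 5 in 100 line and left that for the response over it, so the former is uncertain.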
